A study of Mus musculus with 8 samples.

How the data were processed

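RNA sequencing was done on retinas of 17-day-old C57BL/6J mice with oxygen-induced retinopathy, 4 libraries from retinas given a control scAAV and 4 from retinas given an scAAV that knocks down the long noncoding RNA MM2P. The knockdown group carries a treatment label that reads as a knockout, while the study's description calls it a knockdown. Total RNA was extracted with TRIzol and sequenced as 150-base paired reads on a NovaSeq X Plus, per the labels' protocols. Bowtie 0.12.2 and the mm9 build are named, with no role, per the submitters' processing notes.

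The table deposited by the authors is named for TPM but holds estimated counts per gene, as its values show: the library totals range from 16.03 to 21.4 M (M, 1000000 counts), where TPM would sum to 1000000, and 90.6% to 91.9% of the entries of a library are whole numbers, the rest carrying fractions of a count. The tool that estimated the counts and the rule by which it shared reads between genes are not given in the sources used here. Estimates of this kind are uncertain for near-identical paralogs, such as the γ-crystallin genes or Ifit3 and Ifit3b, and for overlapping genes, such as Mm2pr and Hmgb1. The table lists 57010 Ensembl gene identifiers with a gene length, of which 52029 (91.3%) are found in GENCODE M21 on GRCm38. That annotation was used for positions alone, and the annotation used by the authors is not given. A pair of columns with the authors' group means was left out, since the libraries themselves were used.

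Counts were rounded, and TPM was computed from the estimated counts and the table's gene lengths. Of 29694 genes with a count above 0, the 16118 with at least 1 TPM in at least 4 of the 8 libraries were tested. Knockdown and control libraries were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. TMM scaling and edgeR's default prior count for fold changes were used, with the group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.0959. SE values were derived as the absolute log2 fold change over the square root of edgeR's F statistic. CPM values are counts per 1000000 of the total over the tested genes, scaled by TMM. The limma test on log2(TPM + 1) had been written before the data were examined, for a table of TPM. Because the table held counts, edgeR took its place under a provision written at the same time, and limma was kept as an alternative. The expression filter, the gene lists, the rule for named genes and most of the alternatives were also fixed before the data were examined.

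Genes were named by a fixed rule. It takes the target RNA, the called genes with the 10 largest and 10 smallest log2 fold changes, a conventional gene symbol and no overlap between the groups, and, in a direction with fewer than 5 such genes, the 5 with the smallest p-values that did not pass. It also takes up to 4 called members of each list, or else up to 2 members with the highest TPM, and a fixed panel of macrophage, vascular, glial and photoreceptor genes. Genes outside this rule are given as chosen after their values were seen, and 3 genes that it takes are not reported here.

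The 33 gene lists covered M2-type, M1-type and pan-macrophage genes, angiogenesis, endothelial and pericyte genes, hypoxia, glycolysis, norrin and Wnt signalling, the rod, cone, bipolar, amacrine, horizontal, ganglion and Müller cells, gliosis, retinal pigment epithelium, lens, corneal epithelium, skeletal muscle, erythrocyte, neutrophil, lymphocyte, interferon, antigen presentation, chemokine, extracellular matrix, cell cycle, immediate early, circadian, mitochondrial and ribosomal protein genes. A list was tested when at least 5 members passed the filter, which held for 29. The test was camera of limma 3.58.1 on log2(TPM + 1) with the correlation between genes estimated from the data, two-sided, with p-values adjusted over the lists. Counts of members given as adjusted over the list alone use edgeR p-values adjusted within that list. Values of single measures were compared with exact two-sided permutation tests over all 70 assignments of the libraries.

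The floor of a library is 3 counts over its total. Ratios of summed counts carry 95% exact counting intervals, and these intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The tests were tried on simulated data built on the same genes and library sizes. There edgeR recovered 58.2% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, and 7.65% of its 170 calls fell on unchanged genes. Simulated genes varied independently, only genes above a minimum mean count were changed, and no library was made to stand apart. Recovery in the real libraries may thus be lower.

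The alternatives were limma on log2(TPM + 0.1), log2(TPM + 5) and quantile-normalized values, no expression filter, a mean TPM of at least 5, median-of-ratios scaling, removal of mitochondrially encoded genes, a robust dispersion, no dispersion trend, array weights, the replicate number as a block, and each library left out in turn. Lists were also tested with a preset correlation of 0.01, with fry and with exact permutation. The limma test on log2(TPM + 1) became an alternative once edgeR had taken its place. Added after the data were seen were DESeq2 1.42.0 (Wald test), summed Y-linked expression as a covariate, and a fit without control 3 and knockdown 1. Replicate numbers were not treated as pairs, since the labels do not say that equal numbers share a litter or a day.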

Results

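Retinal RNA was measured in 8 libraries from 17-day-old C57BL/6J mice with oxygen-induced retinopathy, a model in which young mice are kept in high oxygen, lose retinal capillaries, and grow abnormal vessels after return to room air. Each group held 4 libraries: retinas given a control self-complementary adeno-associated virus (scAAV), a gene delivery vector, and retinas given an scAAV directed against the long noncoding RNA MM2P. The comparison asks which transcripts differ when MM2P, a regulator of macrophage polarization, is knocked down in the neovascular retina. Total estimated counts, in units of 1000000 (M), were 20.8 ± 0.446 M (SD, n = 4) in the controls and 18.5 ± 1.78 M (SD, n = 4) in the knockdown libraries, with a range of 16.03 to 21.4 M over all 8. All 4 controls had the larger totals (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give; 0.229 after adjustment over 8 library measures). At these depths 3 counts corresponded to 0.142 to 0.186 counts per 1000000 (CPM) in a library, and 23134 to 23824 genes in 7 libraries and 22895 in knockdown 3 had counts above 0. Xist, which is transcribed from the inactive X chromosome, had 16 counts in control 3 and 21026 to 49127 in the other libraries. The Y-linked helicase Ddx3y had 0 counts in control 1, knockdown 1 and knockdown 3, and 814 to 1919 elsewhere. Controls 2 and 4 and knockdown 2 and 4 had both transcripts, Xist at 137 to 199 TPM (transcripts per 1000000) and Ddx3y at 22.9 to 27.9 TPM. Tissue pooled from both sexes would give this. The labels do not give the sex of the animals, and they do not say whether replicates are separate animals. The sex-linked counts differed within each group, so its libraries do not all come from the same animals. The p-values measure spread between samples, which is thus not technical alone, though it may be technical between some libraries.

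The target transcript was close to its detection limit in both groups. MM2P appears in the table as Mm2pr (ENSMUSG00000097191, macrophage M2 polarization regulator), a long intergenic noncoding RNA matched by its name. Its estimated counts were 1, 1, 16.95 and 7.34 in controls 1 to 4, and 0, 0, 2 and 20.6 in knockdown libraries 1 to 4. These gave 0.441 ± 0.5002 transcripts per 1000000 (TPM; SD, n = 4) in the controls and 0.414 ± 0.712 (SD, n = 4) in the knockdown, a difference smaller than the spread between replicates (exact two-sided permutation p = 0.857). Mm2pr reached 1 TPM in 2 libraries, too few for the expression filter. In an edgeR fit with no filter its log2 fold change was -0.07 (SE 0.79, adjusted p = 0.990). An approximate 95% interval, from this SE and 6 residual degrees of freedom, was -2.01 to 1.87. The width of this interval reflects the uneven counts between libraries as well as their low number. A change of 2-fold in either direction was therefore not excluded, and the target does not check the group labels. In GRCm38 the Mm2pr locus spans positions 149119565 to 149184063 on the minus strand of chromosome 5. It lies inside the same-strand gene Hmgb1 (149046702 to 149184489), which encodes a chromatin protein and shares 37 of the 1856 exonic bases of Mm2pr. The opposite-strand noncoding genes Gm42787 and Gm43332 cover a further 198 and 26 of these bases, so part of the few reads is of uncertain origin.

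**Figure D1:**
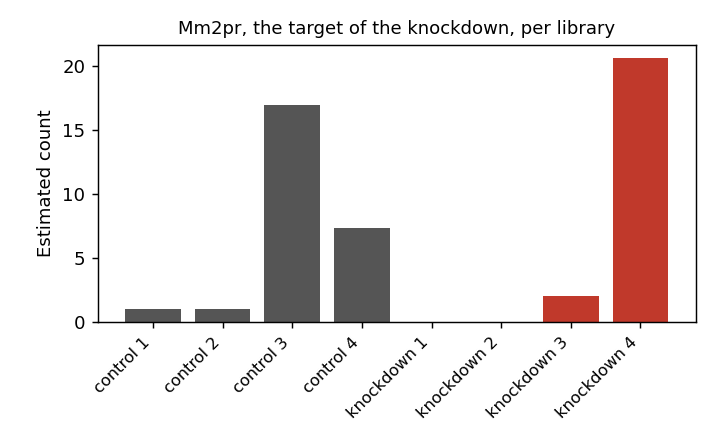
Estimated counts of Mm2pr, the target of the knockdown, in each library, with controls in grey and knockdown libraries in red. Control 3 (16.95 counts) and knockdown 4 (20.6 counts) hold most of the counts of their groups.

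Lens crystallin transcripts rose in the knockdown retinas, while Egr1, Ifit3b and Slc17a6 fell. The 7 genes that rose were Cryaa, Cryba1, Cryga, Crygb, Crygc, Crygd and Cryge, which encode structural crystallins that fill the fibre cells of the lens. Among 16118 tested genes these 10 differed between the groups in edgeR (adjusted p from 0.0186 to 0.0465), 7 higher and 3 lower in the knockdown, and 9 of them by at least 2-fold. In all 10 the 4 knockdown values lay outside the range of the 4 control values, as they did for 534 tested genes (3.31%, where chance gives 2.86%). At an unadjusted p under 0.05 there were 850 genes, 422 higher and 428 lower, against 805.9 expected by chance. The number of genes depended on single controls: it was 0 without control 1 (674 genes at an unadjusted p under 0.05), 0 without control 2 (821 genes), 1 without control 4 and 58 without control 3. The number of genes that fell was 6 without knockdown 1 and 1 without knockdown 4. DESeq2 called 45 genes, all 10 among them, whereas limma on log2(TPM + 1) called 0 with 804 genes at an unadjusted p under 0.05.

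The crystallins went from 1 to 12 counts per gene in the 4 controls to between 135 and 1117 in the 4 knockdown libraries. Cryaa, which encodes the chaperone αA-crystallin (ENSMUSG00000024041; chromosome 17, 31677807 to 31681733), had 0.145 ± 0.136 CPM (SD, n = 4) in the controls and 16.2 ± 16.9 CPM (SD, n = 4) in the knockdown. Its edgeR log2 fold change was 6.73 (SE 0.92, adjusted p = 0.0280), and its summed counts of 12 and 1117 gave a ratio of 104 (95% exact counting interval 59.3 to 202). Cryba1, a β-crystallin gene (ENSMUSG00000000724; chromosome 11, 77718615 to 77725283), had 0.0848 ± 0.0733 CPM and 7.97 ± 9.78 CPM (log2 fold change 6.43, SE 1.05, edgeR adjusted p = 0.0465). The 5 γ-crystallin genes lie in 1 cluster on chromosome 1 (65048554 to 65103373). Their knockdown means ran from 1.84 ± 1.46 CPM for Cryga to 6.87 ± 7.83 CPM for Crygb, against control means of 0.0120 to 0.0605 CPM, and their edgeR adjusted p-values from 0.0280 to 0.0465. Summed control counts were 1 for Crygc, 2 for Cryga, Crygb and Cryge and 5 for Crygd, and the ratios with 95% exact counting intervals were 68.8 (29.2 to 213) for Crygd and 265 (73.0 to 2196) for Crygb. These paralogs are similar in sequence, so the split of reads between them is uncertain. Summed over the 7 genes, the controls had 0.0489 to 0.769 CPM, and the knockdown libraries 29.5, 10.2, 115 and 27.4 CPM. Each of the 7 was picked as called and has no overlap between the groups, so their sum must separate them. All 15 crystallin genes of the lens list, called or not, summed to 33.6 ± 2.11 CPM in the controls and 101 ± 66.3 CPM in the knockdown (SD, n = 4; exact two-sided permutation p = 0.0286).

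Of the 24 members of the lens list 15 were tested. Of these 15, 7 rose over all genes and 14 rose adjusted over the list alone, with a median log2 fold change of 5.91 (5.65 with the 5 genes of 1 to 3 control counts set at the floor of 3 counts). A gene near 0 in the controls passes the expression filter only when all 4 knockdown libraries reach 1 TPM. The shared direction and the median are thus partly set by the filter. The limma camera test gave p = 0.0137 for the lens list, and an adjusted p of 0.370 with an estimated correlation. Cryab, a small heat shock protein gene that the retina also expresses, had 30.4 ± 2.09 CPM and 37.5 ± 9.74 CPM (SD, n = 4) and did not pass. Summed over the 9 other genes of the list, which are not crystallins and include the lens water channel gene Mip, the controls had 3.03 ± 0.632 CPM and the knockdown libraries 5.98 ± 4.58 CPM (SD, n = 4; exact two-sided permutation p = 0.143), with 12.8 CPM in knockdown 3. Cryab and this sum were chosen after their values were seen. The number of lens genes that rose was 0 without control 1, 0 without control 2 and 0 without control 4 (Cryaa log2 fold changes 6.45, 7.52 and 6.73), 1 with Y-linked expression as a covariate, 0 with a robust dispersion and 0 with a mean TPM of at least 5. In edgeR the call of Cryba1 also ended without control 3 (adjusted p = 0.0568), and that of Cryga without knockdown 3 (0.161) and without knockdown 4 (0.107).

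**Figure D2:**
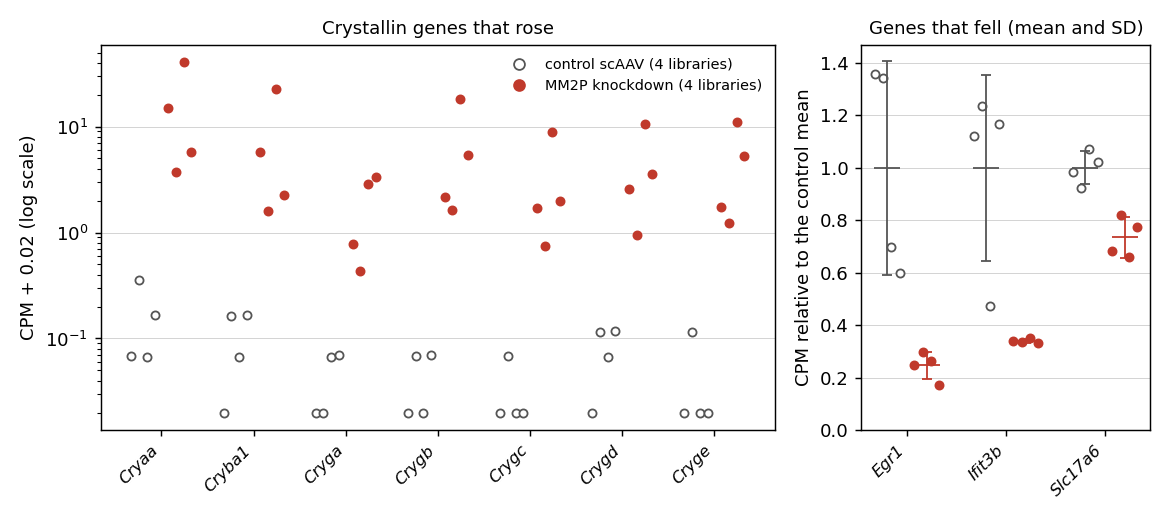
Left, CPM plus 0.02 on a log axis for the 7 crystallin genes that rose, with 1 point per library. Right, CPM relative to the control mean for Egr1, Ifit3b and Slc17a6, which fell, with bars for the mean and SD; the knockdown points of each gene lie outside the range of its controls.

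Egr1, an immediate early transcription factor gene induced by neuronal activity and growth factors (ENSMUSG00000038418; chromosome 18, 34859823 to 34864984), fell from 328 ± 134 CPM (SD, n = 4) in the controls to 80.9 ± 17.3 CPM (SD, n = 4) in the knockdown. Its log2 fold change was -2.02 (SE 0.24, edgeR adjusted p = 0.0186). The controls had 446, 441, 229 and 197 CPM, and the knockdown libraries 57.0 to 97.7 CPM. Of the 12 tested immediate early genes, Egr1 alone fell over all genes, and 4 fell adjusted over the list alone. The other 3, chosen after their values were seen, were Fos at 64.1 ± 21.1 and 35.8 ± 4.79 CPM, Nr4a1 at 57.1 ± 8.36 and 41.0 ± 4.73 CPM, and Ier2 at 21.1 ± 3.38 and 12.8 ± 2.66 CPM. The list had 6 members with positive and 6 with negative fold changes, a median log2 fold change of 0.00 and a mean of -0.29 (limma camera adjusted p = 0.451 with an estimated correlation). The call of Egr1 was lost without control 1 (log2 fold change -1.84, edgeR adjusted p = 0.0633) and without control 2 (-1.85, 0.0727), and the number of list members that fell over all genes was 2 without control 3 and 3 without knockdown 1.

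Slc17a6, which encodes the vesicular glutamate transporter VGLUT2 of retinal ganglion cells (ENSMUSG00000030500; chromosome 7, 51622006 to 51671119), fell from 118 ± 7.40 CPM to 86.9 ± 9.05 CPM (SD, n = 4). Its log2 fold change was -0.44 (SE 0.07, edgeR adjusted p = 0.0465). Slc17a6 was the 1 of 17 ganglion cell markers that fell over all genes, and 3 fell adjusted over the list alone. The additional genes, chosen after their values were seen, were the neurofilament gene Nefl at 616 ± 29.2 and 539 ± 41.1 CPM and the surface glycoprotein gene Thy1 at 190 ± 8.31 and 165 ± 17.1 CPM. Fold changes were negative for 13 of the 17 markers, with a median of -0.12 on the log2 scale (limma camera adjusted p = 0.523 with an estimated correlation). Knockdown 1 had the lowest mean of this list, 5.91 on the log2(TPM + 1) scale against 6.15 to 6.20 in the other knockdown libraries, and without it the median was -0.05. The number that fell adjusted over the list alone was 1 without control 1, 3 or 4 or knockdown 1, 3 or 4, and 4 without control 2 or knockdown 2. The edgeR adjusted p of Slc17a6 was 0.232 without control 1, 0.126 without control 2, 0.146 without control 4, 0.161 without knockdown 3 and 0.0846 without knockdown 4, with log2 fold changes between -0.48 and -0.40.

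Interferon response genes had lower mean levels in all 4 knockdown libraries than in 3 of the 4 controls. Ifit3b, an interferon-induced tetratricopeptide gene (ENSMUSG00000062488; chromosome 19, 34607970 to 34613401), fell from 8.86 ± 3.14 CPM to 3.002 ± 0.0740 CPM (SD, n = 4; log2 fold change -1.56, SE 0.25, edgeR adjusted p = 0.0465). It is a close paralog of Ifit3, so reads shared by both are uncertain. Of the 17 tested genes of the interferon list, 0 fell over all genes in edgeR (15 at an unadjusted p under 0.05), 15 fell adjusted over the list alone, and all 17 had negative fold changes, with a median of -1.32 on the log2 scale. DESeq2 called 5 of them over all genes and limma on log2(TPM + 1) called 0. The limma camera test of the list gave p = 0.0474, and an adjusted p of 0.370 with an estimated correlation. Ifit1, whose product binds foreign RNA, had 8.79 ± 5.44 and 1.31 ± 0.523 CPM (SD, n = 4; log2 fold change -2.73, edgeR adjusted p = 0.107). Isg15, a ubiquitin-like modifier, had 4.08 ± 2.08 and 0.885 ± 0.243 CPM (-2.20, edgeR adjusted p = 0.134). Irf7, a transcription factor of the pathway, had 22.2 ± 9.07 and 19.5 ± 4.67 CPM and did not pass adjusted over the list alone. Slfn5, an interferon-inducible Schlafen gene outside the list, had 18.5 ± 4.44 and 9.47 ± 1.22 CPM (edgeR adjusted p = 0.0738).

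Control 3 stood apart from the other controls in these genes. Its mean over the list was 2.52 on the log2(TPM + 1) scale, against 3.84, 4.31 and 3.70 in controls 1, 2 and 4 and 2.44 to 2.72 in the knockdown libraries. Ifit1, for example, had 1.65 CPM in control 3 and 8.58 to 14.8 CPM in the other controls, and Ifit3b had 4.20 CPM in control 3 and 9.94 to 11.0 CPM in the others. Without control 3, 13 of the 17 list members fell over all genes, and 58 genes were called, 52 of them lower in the knockdown. The call of Ifit3b was kept without control 3 (edgeR adjusted p = 6.72e-05) and without knockdown 1 (0.0450). It was lost without control 1 (0.232), control 2 (0.233), control 4 (0.145), knockdown 2 (0.176), knockdown 3 (0.161) or knockdown 4 (0.133). The other genes with the smallest p-values among those that were lower and did not pass were Scrt2, a neuronal transcriptional repressor gene, at 19.3 ± 0.663 and 13.9 ± 1.16 CPM (edgeR adjusted p = 0.107) and the p53-inducible gene Trp53i11 at 24.3 ± 1.22 and 18.5 ± 0.536 CPM (0.134).

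**Figure D3:**
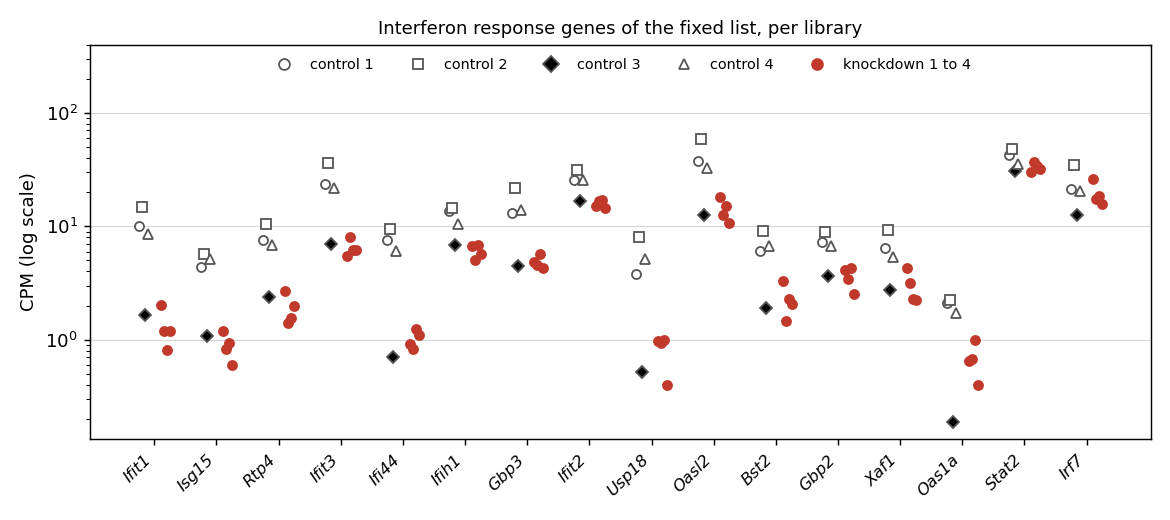
CPM on a log axis of 16 of the 17 tested interferon response genes in each library, with controls in grey or black and knockdown libraries in red. Control 3 (black diamonds) lies near the knockdown libraries, at 1.65 CPM for Ifit1 where the other controls have 8.58 to 14.8 CPM.

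Vascular and hypoxia genes, central to this model, did not pass the test over all genes. In the endothelial list 18 of 19 markers had negative fold changes, with a median of -0.20 on the log2 scale; 9 had an unadjusted edgeR p under 0.05, 0 passed over all genes (0 in DESeq2 and in limma as well) and 0 passed adjusted over the list alone (limma camera p = 0.0493, adjusted p = 0.370 with an estimated correlation). Without knockdown 1, 2 of them fell adjusted over the list alone. The tight junction gene Cldn5 had 35.1 ± 1.34 CPM in the controls and 29.9 ± 2.56 CPM in the knockdown (SD, n = 4), the adherens junction gene Cdh5 36.4 ± 3.17 and 31.3 ± 2.48 CPM, and Pecam1 43.6 ± 3.20 and 41.8 ± 1.74 CPM. In the pericyte and smooth muscle list 10 of 13 genes had negative fold changes and 2 fell adjusted over the list alone (limma camera adjusted p = 0.370 with an estimated correlation). Those genes, chosen after their values were seen, were the proteoglycan gene Cspg4 at 7.78 ± 0.828 and 5.84 ± 0.323 CPM and Higd1b at 2.80 ± 0.637 and 1.56 ± 0.417 CPM. The number that fell was 0 without control 1, control 4, knockdown 2, knockdown 3 or knockdown 4, and 3 without control 2, and without control 1 the fold changes were 6 positive and 7 negative. In the neovascular tuft and tip cell list 16 of 23 genes had negative fold changes, with a median of -0.05 (adjusted p = 0.604 in limma camera with an estimated correlation). That direction rested on single libraries: 11 of 23 were negative without control 1 and 10 without knockdown 3 (median 0.01 each), and 18 without knockdown 1 (-0.16). Vegfa, the main angiogenic growth factor gene of the ischaemic retina, had 292 ± 15.2 and 307 ± 29.4 CPM, its receptor gene Kdr 264 ± 25.1 and 268 ± 11.8 CPM, Angpt2 14.4 ± 2.35 and 13.02 ± 2.27 CPM, and the tip cell gene Esm1 2.87 ± 0.441 and 2.62 ± 1.30 CPM. Hypoxia response genes were split, with 11 positive and 10 negative and a median of 0.01 (limma camera adjusted p = 0.879 with an estimated correlation), among them Ndrg1 at 376 ± 10.8 and 381 ± 27.3 CPM, and Hif1a, the gene of the oxygen-regulated subunit of a hypoxia transcription factor, outside the list, had 969 ± 37.9 and 976 ± 22.2 CPM. Without knockdown 1, 18 of the 21 hypoxia genes were negative, with a median of -0.08, and 18 again with control 3 left out as well. Glycolysis enzymes had 15 of 17 negative fold changes with a median of -0.06 (adjusted p = 0.451 in limma camera with an estimated correlation), and norrin and Wnt signalling genes 6 of 12 (0.906). The glycolysis median was -0.02 without knockdown 3 and -0.11 without knockdown 1.

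Macrophage polarization genes, the proposed field of action of MM2P, also did not pass the test over all genes. In the list of alternatively activated (M2-type) genes 11 of 13 had positive fold changes, with a median of 0.06 on the log2 scale, and 0 passed adjusted over the list alone (limma camera adjusted p = 0.879 with an estimated correlation). This direction was not stable: 6 of 13 were positive without knockdown 1, with a median of -0.10, and 2 of 13 with control 3 left out as well (-0.18), against 11 of 13 without control 1 (0.26). Arg1, the M2-type arginase gene, had 0.762 ± 0.158 CPM in the controls and 3.22 ± 4.52 CPM in the knockdown (SD, n = 4), with 10.003 CPM in knockdown 1, and the mannose receptor gene Mrc1 had 3.02 ± 0.914 and 3.10 ± 0.689 CPM. Among 9 classically activated (M1-type) genes 5 had positive fold changes, and adjusted over the list alone 1 rose, Socs3, and 2 fell, among them Fcgr1, chosen after its values were seen (limma camera adjusted p = 0.818 with an estimated correlation). Socs3, a cytokine signalling suppressor gene, had 2.85 ± 0.299 CPM in the controls (SD, n = 4), 19.5 CPM in knockdown 1 and 2.61 to 5.27 CPM in the other knockdown libraries. Adjusted over the list alone 0 rose without knockdown 1, knockdown 3 or any 1 of the 4 controls, and 1 fell without control 1, 2 or 4 or knockdown 1, 2 or 3. Nos2, the inducible nitric oxide synthase gene, had 1.56 ± 0.228 and 1.80 ± 0.374 CPM. The median of the M1-type list was 0.05 and its mean -0.01, and the median was -0.10 without knockdown 1. Microglia and pan-macrophage markers had 13 of 25 positive fold changes with a median of 0.03 (adjusted p = 0.879 in limma camera with an estimated correlation). Of these 25, 9 were positive without knockdown 1, with a median of -0.12, and 6 with control 3 left out as well (-0.11). Cx3cr1 had 13.4 ± 0.871 and 12.2 ± 1.26 CPM and Aif1 0.861 ± 0.474 and 0.910 ± 0.316 CPM. Cd163, Tnf and Il1b lay below the expression filter, with at most 25, 5 and 6 counts in any library.

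Markers of the retinal neurons differed little between the groups. Rod genes had negative fold changes in 18 of 20 cases with a median of -0.06 on the log2 scale (limma camera adjusted p = 0.370 with an estimated correlation); the transducin gene Gnat1 had 7539 ± 221 and 6833 ± 492 CPM (SD, n = 4). The rod median was -0.03 without knockdown 3, and 14 of 20 rod genes were negative without control 4. Negative fold changes were found for 10 of 14 cone genes (0.451), 13 of 15 amacrine genes (0.604), 5 of 8 horizontal cell genes (0.879) and 0 of 16 bipolar cell genes, whose median was 0.04 (0.394), with the limma camera adjusted p for an estimated correlation in brackets. Negative amacrine genes numbered 8 of 15 without knockdown 1, where the median went from -0.07 to 0.00, and negative cone genes 8 of 14 without control 4. Horizontal cell genes were 4 positive and 4 negative without control 3, and 4 of 16 bipolar cell genes were negative without control 1, control 4 or knockdown 4, while the bipolar median was 0.07 without control 2. Among amacrine genes the vesicular GABA transporter gene Slc32a1 fell adjusted over the list alone, at 69.7 ± 2.66 and 61.2 ± 2.33 CPM. Müller glia markers had 8 of 14 positive fold changes (adjusted p = 0.523 in limma camera with an estimated correlation), and 6 of 14 without control 2, with the glutamine synthetase gene Glul at 2828 ± 159 and 2733 ± 185 CPM, and the Notch target gene Hes1 rose adjusted over the list alone, at 12.4 ± 0.824 and 15.4 ± 0.832 CPM. Slc32a1 and Hes1 were chosen after their values were seen. No amacrine gene fell adjusted over the list alone without control 1, 2 or 3 or knockdown 1, 2 or 3, and no Müller gene rose without control 1, 2 or 3 or knockdown 1 or 3.

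Reactive gliosis genes were high in 1 knockdown library. In that list 18 of 19 genes had positive fold changes with a median of 0.42 on the log2 scale, 10 had an unadjusted edgeR p under 0.05, and 0 passed over all genes or adjusted over the list alone (limma camera adjusted p = 0.604 with an estimated correlation). The intermediate filament gene Gfap had 51.6 ± 12.3 CPM in the controls, 135 CPM in knockdown 1 and 32.3 to 45.4 CPM in the other knockdown libraries. The lipocalin gene Lcn2 had 122.6 CPM and the serpin gene Serpina3n 138.8 CPM in knockdown 1, both chosen after their values were seen, against 1.98 to 7.66 CPM and 4.49 to 7.93 CPM in the other 7 libraries. Without knockdown 1 the median of the list was 0.08, with 11 of 19 genes positive, while adjusted over the list alone 8 genes rose without knockdown 2, 7 without knockdown 3 and 12 without knockdown 4.

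Markers of tissue next to the retina and of blood did not pass as lists tested for a shared direction. The pigment epithelium list, with members moving both ways, had an unadjusted p of 1.4e-05 in fry for mixed directions. The retinal pigment epithelium and melanocyte list had 6 positive and 6 negative fold changes, with a median of -0.06 and a mean of 0.03 on the log2 scale (limma camera adjusted p = 0.879 with an estimated correlation). Adjusted over the list alone the pigment genes Tyr (7.09 ± 0.719 and 9.64 ± 0.956 CPM; SD, n = 4), Dct (44.4 ± 5.30 and 53.8 ± 6.86 CPM) and Pmel (9.95 ± 3.15 and 14.3 ± 2.64 CPM) rose. The visual cycle genes Rdh5 (10.1 ± 0.886 and 7.54 ± 1.01 CPM) and Lrat (13.1 ± 1.91 and 9.82 ± 0.977 CPM) and the transcription factor gene Mitf (7.12 ± 0.874 and 5.15 ± 0.668 CPM) fell adjusted over the list alone. These 6 genes other than Dct were chosen after their values were seen. Adjusted over the list alone the number that rose was 1 without control 2, control 3, knockdown 2 or knockdown 4 and 5 without control 4, and the number that fell was 1 without control 3, 5 without control 1 and 6 without knockdown 1. Erythrocyte genes had 5 of 5 positive fold changes with a median of 0.31 (limma camera adjusted p = 0.451 with an estimated correlation), with the globin gene Hbb-bs at 46.6 ± 8.58 and 57.9 ± 15.2 CPM, and the median was 0.19 without knockdown 1. Too few members were tested of the corneal and conjunctival epithelium list (Perp), the skeletal muscle list (Acta1 and Mylpf), the neutrophil list (Mmp9 and Csf3r) and the lymphocyte list (Lck and Cd8a) for a list test, and none of these genes passed.

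The remaining lists did not pass either. Antigen presentation genes had 9 of 14 negative fold changes, with a median of -0.15 and a mean of 0.04 on the log2 scale (limma camera adjusted p = 0.879 with an estimated correlation), and the invariant chain gene Cd74 rose adjusted over the list alone, at 1.09 ± 0.297 and 2.17 ± 0.531 CPM (SD, n = 4). The clock output gene Dbp fell adjusted over the list alone, at 89.3 ± 2.26 and 79.0 ± 1.17 CPM, in a circadian list with 8 of 15 negative fold changes (0.818 in limma camera with an estimated correlation). Cd74 and Dbp were chosen after their values were seen. Adjusted over the list alone no antigen presentation gene rose without control 1, 2 or 3 or knockdown 3 or 4, and 3 fell without knockdown 1. In the circadian list 0 fell without control 1, control 4 or knockdown 3, and 2 without knockdown 2 or knockdown 4. Negative fold changes were found for 7 of 10 chemokine, cytokine and adhesion genes (0.604), 15 of 20 extracellular matrix genes (0.604), 6 of 18 cell cycle genes (0.818), 5 of 13 mitochondrially encoded mRNAs (0.879) and 14 of 40 ribosomal protein genes (0.906), again with the limma camera adjusted p in brackets. The direction of each turned on single libraries. Negative fold changes numbered 4 of 10 for the chemokine list without control 2, 9 of 20 for the matrix list without control 1, and 10 of 18 for the cell cycle list without control 2. They numbered 12 of 13 for mitochondrial mRNAs without control 2 and 1 of 13 without control 4, and 36 of 40 for ribosomal genes without knockdown 1 and 0 of 40 without control 4. Over all 29 tested lists, camera with an estimated correlation called 0 (lowest adjusted p = 0.370 in limma, with 3 lists at an unadjusted p under 0.05). Fry for a shared direction called 0. The exact permutation test also called 0, but the lens list, at its smallest two-sided p of 0.0286, had an adjusted p of 0.331. It could thus hardly call a list. Fry for mixed directions was not adjusted over the lists. Its p-values were lowest for the pigment epithelium (1.4e-05), lens (0.00260), pericyte (0.00281) and immediate early (0.00301) lists. With a preset correlation of 0.01 camera called 13 lists: endothelial, pericyte, angiogenesis, glycolysis, rod, bipolar, amacrine, ganglion cell, gliosis, lens, erythrocyte, interferon and immediate early genes. None of these 13 held with an estimated correlation.

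**Figure D4:**
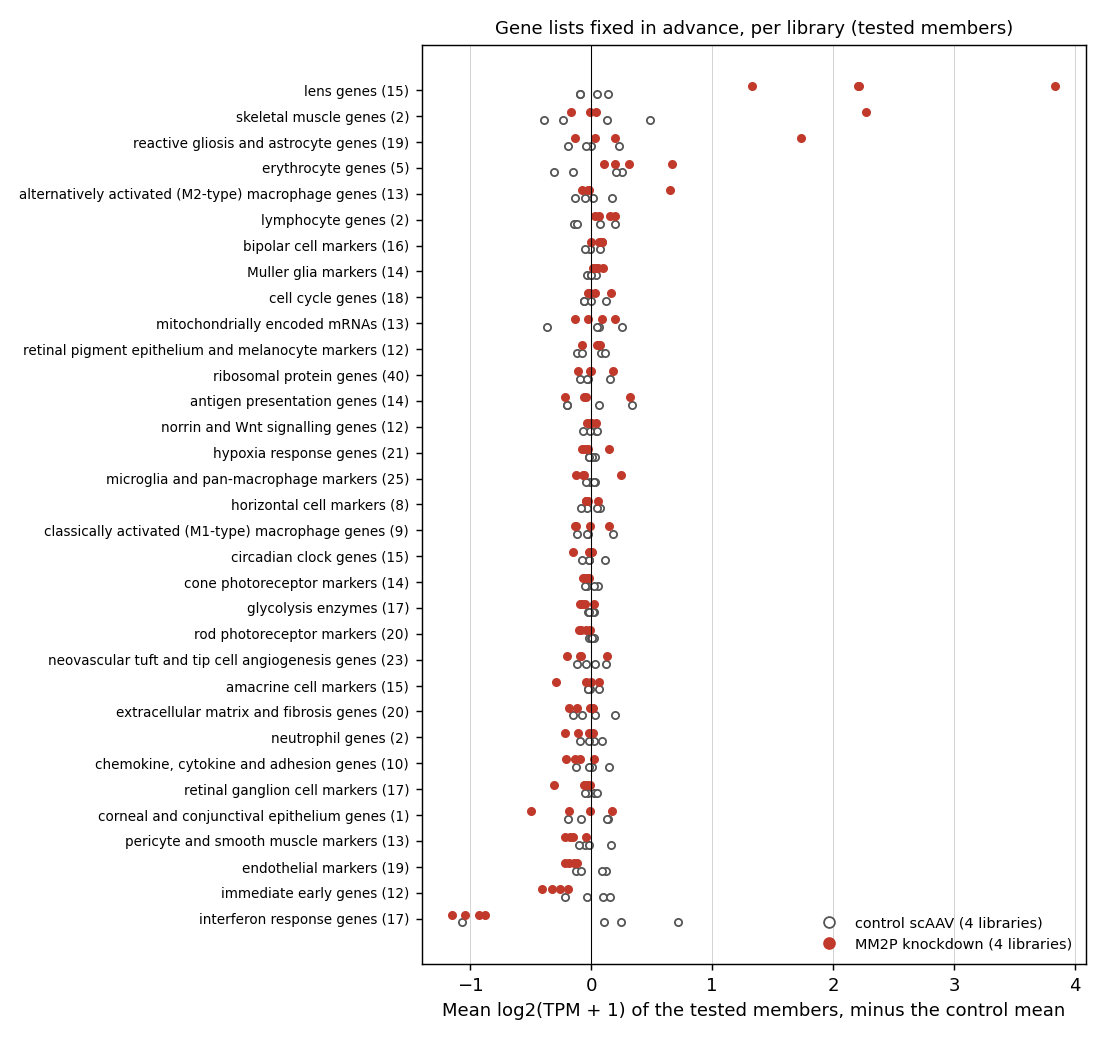
Mean log2(TPM + 1) over the tested members of each of the 33 gene lists in each library, minus the mean of the controls, with controls as open grey and knockdown libraries as filled red points. The lens list lies above 0 in all knockdown libraries, and the interferon list lies below 0 in all of them and in control 3.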

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

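The tests of 3 patterns, on lens tissue, gliosis, sex, microglia, read depth, a wrong label and shared reads, were chosen only after the results were seen, while the counts over other splits of the libraries had been planned.

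The 7 called crystallins rose in all 4 knockdown libraries and were near the floor in all 4 controls. All 15 crystallins of the lens list, among them Cryab, summed to a mean of 33.6 CPM in the controls and 101 CPM in the knockdown. Of the other 34 splits of the 8 libraries, 0 gave as many genes higher in a group (7 for the real split, at most 5 for another). This argues against chance for their number. It does not exclude chance, since 1 in 35 splits is the smallest share possible and these genes rose together. A glial stress response that raises crystallins together with gliosis genes is argued against, since the gliosis list lay above the highest control in 1 of the 4 knockdown libraries. Lens tissue taken with the retina could be a source: the 9 other lens genes, summed, lay above the highest control (3.77 CPM) in 3 of the 4 knockdown libraries, with Mip at 5.33 CPM in knockdown 3 against 0.208 to 0.769 CPM elsewhere, but at 2.76 CPM in knockdown 2, where the 7 crystallins summed to 10.2 CPM, the lowest of that group. Sex of the animals stays open. Summed over the 7 called crystallins, the lowest knockdown library had 13.2 times the CPM of the highest control among 5 libraries with Ddx3y counts. Among 3 without, it had 602 times, from few control counts. Of the 5 libraries, control 3 had almost no Xist, while the highest control was control 2, which had both Xist and Ddx3y. The 7 crystallins were picked as higher in the knockdown, which favours such ratios. Over all 15 crystallins the lowest knockdown and the highest control had 46.5 and 36.7 CPM with Ddx3y counts, and 94.9 and 33.1 CPM without. With Y-linked expression as a covariate 1 lens gene rose in place of 7, with a list median log2 fold change of 5.44 against 5.91. Lens RNA and a crystallin response of retinal cells to the knockdown cannot be told apart here, given the few counts of the other lens genes, and a difference in dissection or vector preparation between the groups was not tested.

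The interferon list had a lower mean in the 4 knockdown libraries and control 3 than in the other 3 controls, with 0 of 17 members past the test over all genes and an adjusted p of 0.370 in limma camera with an estimated correlation. Fewer microglia and macrophages in the knockdown retinas are argued against, since the median log2 fold change of the microglia list was 0.0273 (SD of its members 0.23) where that of the interferon list was -1.32, and -0.12 against -1.46 without knockdown 1. With Y-linked expression as a covariate, 16 of the 17 list members still passed adjusted over the list alone. That count is a weak test of sex. The members move together (estimated correlation 0.878), and the covariate is highest in control 3, the lowest control. Without Ddx3y counts, the list mean was 3.84 in control 1 and 2.72 and 2.67 in knockdown 1 and 3. With them, it was 4.31 and 3.70 in controls 2 and 4 and 2.555 and 2.44 in knockdown 2 and 4. These means argue against sex of the animals as the whole cause, although control 3 is the library with the lowest Xist and the highest Ddx3y. For the 3 genes that fell over all genes chance is not excluded, since 2 of the 35 splits gave as many, with up to 5 in another split. A lower response to the knockdown vector, or a higher response to the control vector preparation in 3 of 4 libraries, may each account for the pattern, and the design gives no test between them.

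The target RNA showed no detectable difference between the groups, and 20.6 of its counts were in knockdown 4, where the other 3 libraries of that group had 0 to 2. Few reads on the target, spread unevenly between libraries, may account for this, since the 95% interval of its log2 fold change reached down to -2.01. Of the 7 genes called without knockdown 4, 7 placed that library on the knockdown side. They were Egr1 and 6 crystallin genes, which rose together and could come from lens tissue. A wrong label on knockdown 4 is thus argued against by few separate signals. Among them, Egr1 had 57.0 CPM in knockdown 4 and 197 to 446 CPM in the controls. Reads of the overlapping Hmgb1 transcript stay open as a source. The target varied around a constant share of Hmgb1 with a chi-square over degrees of freedom of 11.0, more than counting error alone would give. This does not decide the question. The spread between libraries at so few counts was not measured, and the rule by which reads were shared between the genes is not given. Whether the knockdown lowered MM2P thus stays open in these data.

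For independent, normally distributed values, chance alone sets 1 library apart from the other 3 of its group in about 1 of 20 groups. That would be 12.7 of the 254 groups examined, and 27 were found, 10 of them in knockdown 1. The values were not independent, since genes and list means overlap, and some groups of CPM values were 0 in all but 1 library. The count of 27 is thus not a measure of an excess over chance. In knockdown 1, Arg1 (10.003 CPM), Socs3 (19.5 CPM), Cp (367 CPM), Hbb-bs (80.8 CPM), Gnb3 (397 CPM) and Gfap (135 CPM) were far above the other knockdown libraries, and Lrtm1 (235 CPM) was below them. The list means of that library stood apart as well, on the log2(TPM + 1) scale, with 2.59 for M2-type genes above the others, and 5.91 for ganglion cell markers and 5.30 for circadian genes below. In knockdown 3, Crygc (8.93 CPM), Rgs5 (320.2 CPM), the other lens genes summed (12.8 CPM) and the horizontal cell list mean (3.23) were high, and Dct (43.6 CPM) and Pecam1 (39.2 CPM) were low. In knockdown 4 the muscle genes Acta1 (9.52 CPM) and Mylpf (6.99 CPM) and the muscle list mean (4.35) were high. In control 2, Cryge (0.0961 CPM) and Crygc (0.0481 CPM) had the only counts among the controls, and H2-D1 (66.7 CPM) and Pax6 (332 CPM) were high. In control 3, Ifit3b (4.20 CPM) was low and Opn1sw (351 CPM) high, and in control 4, Sparc (725 CPM) was high.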

How the results depend on the processing

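DESeq2, the Y-linked covariate and the fit without control 3 and knockdown 1 were chosen only after the data were seen; the other alternatives were planned, and limma on log2(TPM + 1) had been written as the first test, for a table of TPM, before edgeR took its place. Numbers of genes that differed, that were higher, that were lower and that differed at least 2-fold are given in this order, against 10, 7, 3 and 9. The planned settings gave 9, 8, 1 and 9 with limma on log2(TPM + 0.1), 0, 0, 0 and 0 with limma on log2(TPM + 5) (802 genes at an unadjusted p under 0.05), 157, 64, 93 and 98 with no filter on low values, and 1, 0, 1 and 1 with a mean TPM of at least 5. They gave 0, 0, 0 and 0 with limma on quantile-normalized values (877 at an unadjusted p under 0.05), 0, 0, 0 and 0 with a robust dispersion (833), 5, 4, 1 and 5 with no trend of the quasi-dispersion, and 4, 3, 1 and 4 with limma and array weights. Limma on log2(TPM + 1) gave 0, 0, 0 and 0 (804). The added settings gave 45, 16, 29 and 21 with DESeq2, 3, 1, 2 and 3 with Y-linked expression as a covariate, and 69, 10, 59 and 53 with control 3 and knockdown 1 both left out. Median-of-ratios scaling and removal of mitochondrially encoded genes each kept the same 10 genes. The replicate block gave 11, 9, 2 and 11, with 8 of the 10 genes shared, and libraries of equal number correlated at -0.112 to 0.00910 around their group means, so no pairing was seen. Leaving out 1 library gave 0 to 58 genes that differed, 0 to 9 higher, 0 to 52 lower and 0 to 47 at least 2-fold; the lowest were without control 1 or control 2 (0 each) and the highest lower count was without control 3. The no-filter fit tested 29582 genes and kept all 10, DESeq2 kept all 10, and the fit without control 3 kept 9. Fewer libraries take part when 1 is left out; for the other moved results the cause was not tested. Lists called for a shared direction stayed at 0 in the alternatives run for the lists, which leave out DESeq2 and the dispersion settings, except the preset correlation, which gave 13. It sets a smaller correlation than was estimated for those lists, but this is not the whole cause of the gap. The Gene Ontology term neuropeptide hormone activity had an estimated correlation of -0.00674, below the preset one. Its unadjusted p in limma camera was still 7.57e-06 with the preset correlation and 0.00341 with the estimated one. The target RNA kept a difference within its spread, from -0.57 to 0.26 on the log2 scale, against -0.08. Of single-gene results 1722 stayed on their side of the threshold or within their spread, 108 no longer passed, 24 newly passed and 17 moved by more than their spread, and 0 reversed. Egr1 kept its call in 17 of 23 alternatives, Cryaa in 15, Ifit3b in 8 and Slc17a6 in 7. The splits argue against chance for the number of genes that differed, 10 in all (at most 5 in another of the 35 splits, with 1 split as large, the real one). The same holds for the number at least 2-fold, 9 (at most 1 in another). Chance is not excluded for either, since 1 in 35 splits is the smallest share possible. For the 3 that were lower the splits do not argue against it (2 of 35 splits, up to 5 in another). For the lists, where the real split called 0, as did all 35 splits, the count has no bearing on chance. Depth limits the crystallins in the controls, which had 1 to 12 counts summed over 4 libraries. The target RNA is limited by few counts that were uneven between libraries.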

Other observations

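The tests over Gene Ontology terms in this part, and the choice of the genes and libraries it names, were made only after the results were seen. Among 2829 terms of 10 to 300 genes, 12 were called by limma camera with a preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.9998). Outside the lens and interferon groups, the genes of neuropeptide hormone activity had negative fold changes in 10 of 10 cases, with an adjusted p of 0.00306 in limma with the preset correlation and 0.9998 with an estimated one (0.00341 unadjusted). They included Cartpt, the gene of a neuropeptide of the retina and brain, at 40.2 ± 3.35 CPM in the controls and 31.5 ± 4.19 CPM in the knockdown (SD, n = 4), and Vgf, a gene of a secreted neuronal protein, at 15.7 ± 3.93 and 10.03 ± 2.58 CPM. Phototransduction genes had negative fold changes in 18 of 20 cases, with an adjusted p of 9.56e-04 in limma with the preset correlation and 0.9998 with an estimated one (0.0127 unadjusted). Genes of the voltage-gated potassium channel complex had 41 of 53 negative fold changes, among them Kcna4 at 14.3 ± 0.295 and 11.4 ± 1.003 CPM. Their adjusted p in limma camera was 0.00867 with the preset correlation and 0.9998 with an estimated one (0.181 unadjusted). None of the genes named here passed over all genes.

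Without control 3, the control lowest in the interferon list, 45 of the 58 genes that edgeR called were outside that list, and no list or term was tested on them. These 45 are not a set apart from the interferon response. They include the interferon-induced genes Ifit3b and Slfn5, and Rigi, which the list holds only under its older symbol Ddx58. The immunity-related GTPase genes Irgm1 (log2 fold change -1.61, edgeR adjusted p = 4.50e-04) and Iigp1 (-2.85, 4.68e-04) fell in that fit, as did the ubiquitin ligase gene Rnf213 (-1.25, 8.78e-04) and the lipocalin gene Apod (-1.19, 4.68e-04). Fos, an immediate early gene, fell by 0.96 on the log2 scale (edgeR adjusted p = 0.0443).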
